A study of Mus musculus with 12 samples.

How the data were processed

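Expression was read from a deposited table of RSEM expected counts and a deposited table of FPKM, each with 55413 genes and the same 12 libraries. The unit of the first is expected counts per gene per the submitters' processing notes, and the unit of the second is FPKM, fragments scaled to transcript length and library size, per the same notes. Both units were checked against the values before any test, and no column was left unused. Per the submitters' processing notes reads from BGISEQ-500 runs of total RNA were aligned with STAR 2.7.11a to GRCm38/mm10 and quantified with RSEM 1.3.3, and DESeq2 was named for differential expression. The gene annotation behind the deposited tables is not given in the sources used here. Gene positions were taken from GENCODE vM21 (GRCm38), in which 53292 of the gene symbols were found.

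Expected counts were rounded to whole numbers for the tests. Of 27279 genes with any count 15705 passed filterByExpr of edgeR by group and were tested. Tests used R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0. The main test was the edgeR quasi-likelihood F test with TMM factors, all 12 libraries in 1 fit and group as the only factor, and every adjusted p is a Benjamini-Hochberg value within 1 comparison. A gene was called at an adjusted p below 0.05. CPM values use the deposited library totals and are given as mean ± SD over libraries. Mitochondrial transcripts made up 4.00 ± 0.074% of counts in lymph node Treg, 4.46 ± 0.18% in tumor pTreg and 5.11 ± 0.20% in tumor tTreg, and the square root of the common dispersion within those groups was 0.0314, 0.0240 and 0.0335. The pan-T counts per library were 98888 to 118297, 25388 to 25654 and 2402 to 2499, so levels per pan-T count rest on few T cell counts in tumor tTreg.

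Gene lists were fixed in advance and drawn from general knowledge: Treg core, thymic Treg, Th1, Th2, Th17, follicular helper, purine metabolism, tumor Treg, co-inhibitory and co-stimulatory receptors, suppressive effectors, cytotoxic granule, naive and lymph node homing, chemokine receptors, type I interferon, interferon gamma, cell cycle, glycolysis, hypoxia, oxidative phosphorylation, lipid and cholesterol synthesis, fatty acid use, T cell receptor and NF-kB activation, dissociation stress, TGF-beta, IL-2 and STAT5, ribosomal protein and mitochondrially encoded genes, sex-linked genes, and markers of Hepa1-6 cells or hepatocytes, macrophages and monocytes, neutrophils, dendritic cells, B cells, plasma cells, CD8 T cells, NK and innate-like T cells, fibroblasts, endothelium and erythroid cells. These 40 lists were tested with camera of limma on TMM log2 CPM (prior count 2, preset correlation 0.01) where at least 3 members were measured, with Benjamini-Hochberg adjustment over the lists of a comparison. Camera asks whether members rank higher or lower than other genes. The alternatives were camera with a correlation estimated per list, and fry, which does not compare with other genes.

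Genes named in the text follow a rule. It takes 14 genes set by the question of the series (Foxp3, Entpd1, Nt5e, Tbx21, Cxcr3, Ifng, Ikzf2, Nrp1, Il2ra, Ctla4, Ptprc, Il10, Ccr8 and Pdcd1), and the 8 largest changes in each direction among called genes with at least 10 CPM in the higher group and no overlap between groups. It further takes up to 4 members with the smallest p of each list and the 2 most abundant members of each marker list. A few genes that meet the rule are not reported here. Predicted genes, pseudogenes, immunoglobulin and T cell receptor segments and mitochondrial genes were left out of the largest changes. The pan-T list and the scalings to its counts and to those of the 4 CD3 genes were chosen after the values were seen. A gene without counts in a group was given a floor of 3 counts over the group, and genes with 1 to 3 counts were given a ratio of counts with a 95% binomial interval.

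The alternatives set in advance were RLE factors, library totals only, no filter, a filter at a mean of 5 CPM, DESeq2, limma-voom with quality weights, limma-trend on log2 of FPKM + 1 and of FPKM + 0.1 and with a filter at a mean FPKM of 1, fits of the compared groups only, a threshold of 1 on the absolute log2 fold change, robust dispersion, a replicate block, and each library left out in turn. The replicate numbers were also checked for pairing on 9623 genes. The p-values and folds of the edgeR test were tested on simulated data, with 50 of 15705 genes changed at each of 4 fold sizes. At 1.25, 1.5, 2 and 4-fold the test recovered 64, 72, 88 and 100% in the comparison of the tumor groups, 68, 76, 90 and 94% for tumor pTreg against lymph node Treg, and 64, 86, 86 and 96% for tumor tTreg against lymph node Treg. False calls were 3.26, 2.21 and 4.69% of all calls. Most genes were unchanged in these simulations, whereas 52.1, 87.5 and 90.3% of genes were called in the real comparisons. The rates therefore do not test the TMM scaling where most genes differ. Reads were not used here, and splicing, T cell receptor sequences and strain variants were not analysed here.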

Results

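Bulk RNA sequencing was used to compare regulatory T cells (Treg cells, CD4 T cells that depend on the transcription factor Foxp3 and restrain other immune cells) from mouse tumors with those of lymph nodes. Hosts lacking T cells (TCRbd-/-) were given Treg cells of thymic origin (tTreg, CD45.1), conventional CD4 T cells (CD45.2) and CD8 T cells in proportions of 1 to 10 to 8. Hepa1-6 cells, a mouse hepatoma line, followed 3 days later, and Treg cells were sorted from tumors 18 days after inoculation. The series holds 12 libraries: 3 of tumor Treg cells converted from conventional CD4 T cells (tumor pTreg), 5 of tumor tTreg and 4 of total Treg cells from lymph nodes of tumor-free mice. Depth was 18.0 to 18.2 M counts in tumor pTreg, 18.1 to 18.5 M in tumor tTreg and 14.6 to 17.3 M in lymph node Treg, where 20886 ± 24, 20653 ± 48 and 18754 ± 220 genes were detected. Each library was kept as 1 replicate. Libraries of a group differed by more than counting noise (chi-square per degree of freedom 1.65 to 3.97 over all pairs), which does not show that they are separate animals. The spread within groups was small (square root of the common dispersion 0.0240 to 0.0335). The labels do not say that the libraries came from separate animals, and the p-values measure a spread between libraries that may be technical.

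Transcripts of T cells made up very different shares of the 3 kinds of libraries. The summed level of 18 pan-T genes, which encode CD3 chains, T cell receptor constant regions and signalling proteins such as Lck, was 6766 ± 53.3 CPM (counts-per-million) in lymph node Treg (n = 4), 1414 ± 16.3 in tumor pTreg (n = 3) and 134 ± 2.41 in tumor tTreg (n = 5). All 18 fell against lymph node Treg, by a median of 4.95-fold in tumor pTreg (range 2.18 to 9.68) and of 49.2-fold in tumor tTreg (range 31.0 to 102). Lck, the kinase that starts T cell receptor signalling, read 819 ± 17.7, 159 ± 3.90 and 13.9 ± 1.38 CPM in lymph node Treg, tumor pTreg and tumor tTreg. Marker genes of Hepa1-6 cells or hepatocytes summed to 25.3 ± 1.73 CPM in lymph node Treg, 9696 ± 163 in tumor pTreg and 12160 ± 238 in tumor tTreg, and those of macrophages and monocytes to 39.7 ± 3.51, 6261 ± 28.3 and 6507 ± 135. B cell markers went the other way, at 409 CPM in lymph node Treg, 65.7 in tumor pTreg and 68.7 in tumor tTreg. Levels are therefore given on a pair of scales: CPM of the whole library, and counts per 100 pan-T counts. Whether sort purity, carried-over RNA or an amplification step was assessed is not given in the sources used here. On the second scale a gene that other cells also express does not read as a T cell level. The pan-T list, this second scaling and a scaling to the 4 CD3 genes were chosen after the data were examined; groups, comparisons, gene lists, main tests and the other alternatives were fixed before the data were examined.

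**Figure D1:**
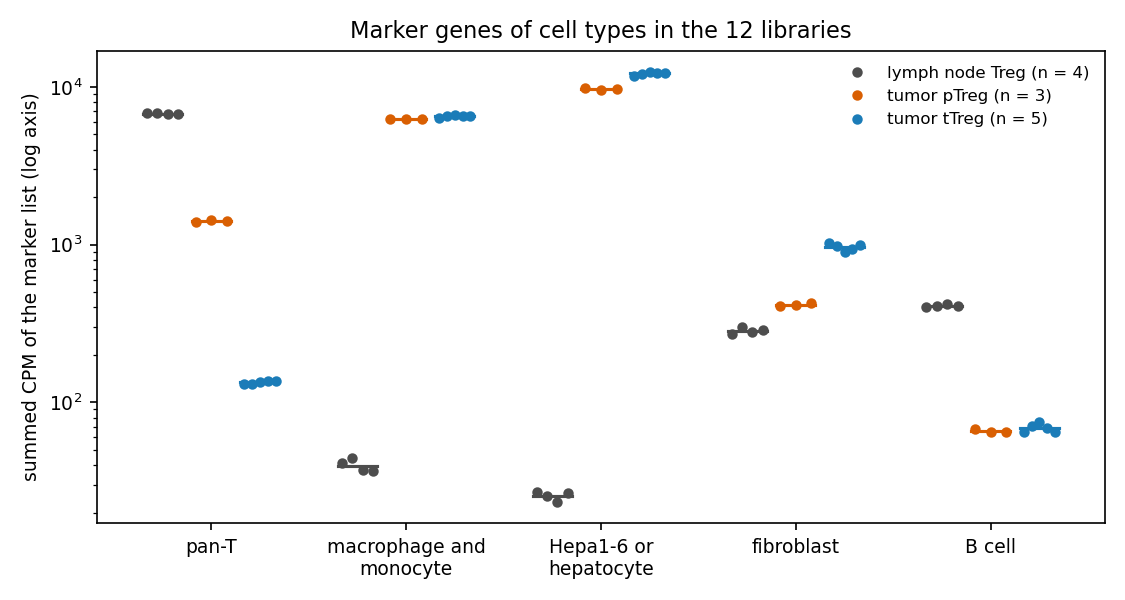
Summed CPM of 5 marker lists in each of the 12 libraries on a log axis. Points are libraries of lymph node Treg (n = 4), tumor pTreg (n = 3) and tumor tTreg (n = 5), and lines are group means. Pan-T genes fell from lymph node Treg to tumor pTreg and further to tumor tTreg, while macrophage and hepatocyte markers were high in both kinds of tumor libraries.

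How do Treg cells converted from conventional T cells differ from tTreg in the same kind of tumor? Ifng, the effector cytokine of Th1 cells, reached 102.6 ± 1.69 CPM in tumor pTreg (n = 3) against 2.81 ± 0.534 in tumor tTreg (n = 5), a log2 fold change of 5.19 (standard error 0.0711, adjusted p = 2.85e-29). Tbx21, which encodes T-bet, the transcription factor that drives Th1 cells, read 34.5 ± 1.19 against 1.78 ± 0.434 CPM (log2 fold change 4.28, adjusted p = 7.68e-25). Both stayed higher in tumor pTreg when libraries were scaled to pan-T counts, at log2 fold changes of 1.79 for Ifng and 0.88 for Tbx21. Pdcd1, the gene of the inhibitory receptor PD-1, was 23.3-fold higher (48.9 ± 1.28 against 2.10 ± 0.260 CPM) and also stayed higher per pan-T count (1.14). Cxcr3, a Th1 chemokine receptor, was higher by CPM (log2 fold change 2.45) but lower per pan-T count (-0.96).

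Among genes with at least 10 CPM in the higher group and no overlap between the groups, Il21, a cytokine of follicular helper cells, rose most in tumor pTreg. It read 10.3 ± 0.387 against 0.0989 ± 0.106 CPM (98.3-fold). Eomes, a T-box factor of cytotoxic lymphocytes, followed at 16.4 ± 0.877 against 0.208 ± 0.0712 (76.9-fold), then Klrc1, the NKG2A receptor chain (66.9-fold), and Gzmk, a granzyme (63.1-fold). Apol7e (53.4-fold), Fasl (40.8-fold) and Tnfsf11, which encodes RANKL (35.2-fold; 78.4 ± 1.17 against 2.23 ± 0.343 CPM), came next beside Ifng. All of these stayed higher per pan-T count, from 1.74 for Tnfsf11 to 3.30 for Il21. The genes furthest lower in tumor pTreg, under the same limits, were Dpt (log2 fold change -3.87), Col3a1 (-3.80; 22.3 ± 4.08 against 312 ± 22.9 CPM), Serpina3n (-3.46), Cpxm1 (-3.45), Tnxb (-3.32), Efemp1 (-3.14), Col1a2 (-2.98) and Col1a1 (-2.85). Across the 15705 genes tested 4204 were higher and 3980 lower in tumor pTreg, whereas lower genes outnumbered higher ones with RLE factors (3572 higher and 4872 lower) and with DESeq2 (3328 and 4315). Scaling to pan-T counts turned the split to 80 higher and 15266 lower, with a median shift of -3.41. By at least 2-fold 1031 genes were higher and 222 lower.

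The Th1 program rose as a list: 23 of 26 measured members were higher and 1 lower in tumor pTreg, with the same counts when p-values were adjusted over the list alone (camera FDR 5.1e-15). Among them were Cxcr6, a chemokine receptor of tissue T cells (62.0 ± 3.37 against 1.91 ± 0.472 CPM, 32.5-fold), Nkg7, a granule protein (26.4-fold), and Il18rap, a chain of the IL-18 receptor (10.7-fold). Per pan-T count 8 Th1 members were higher and 17 lower, with Cxcr6 at 1.62, Nkg7 at 1.32 and Il18rap level at 0.01 (adjusted p = 0.905). Among all 15705 genes tested 80 were higher and 15266 lower on that scale. The pan-T genes themselves rose by a median of 11.4-fold in the same libraries (range 6.05 to 16.8). Of 12 cytotoxic granule genes 11 rose and 1 fell (FDR 2.92e-08), and 5 against 4 did so per pan-T count. Gzmb rose 5.08-fold by CPM but was lower per pan-T count (-1.06), and Ctsw, a cathepsin of cytotoxic cells, rose 11.7-fold but was level per pan-T count (0.14, adjusted p = 0.129). Cd8a and Cd8b1, the chains of the CD8 co-receptor, read 23.6 ± 0.942 and 9.22 ± 0.902 CPM in tumor pTreg against 0.667 ± 0.186 and 0.438 ± 0.160 in tumor tTreg, and were higher per pan-T count as well (1.74 and 0.997). This CD8 list has 2 members and was not tested as a list.

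Other helper programs rose too. All 9 measured Th2 genes were higher in tumor pTreg (FDR 2.81e-07), with Il13 at 7.21 ± 0.651 against 0.0437 ± 0.0457 CPM, and 9 of 11 follicular helper genes rose with none lower (FDR 9.44e-07), with Cd40lg at 22.6 ± 0.348 against 0.711 ± 0.161. Il13 (3.95) and Cd40lg (1.59) stayed higher per pan-T count, whereas the Th2 list split into 2 higher and 7 lower and the follicular list into 4 higher and 5 lower. In the Th17 program 6 of 10 rose and 3 fell (4 by the list alone; FDR 0.0236), and with an estimated correlation between genes the adjusted p was 0.0658, while per pan-T count 2 Th17 genes were higher and 8 lower. Il17a was its largest named example, at 3.56 ± 0.178 against 0.0548 ± 0.0670 CPM.

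The Treg program was higher in tumor pTreg by CPM and lower per pan-T count. Foxp3 read 20.3 ± 0.583 CPM in tumor pTreg and 8.74 ± 0.478 in tumor tTreg (log2 fold change 1.23, adjusted p = 3.87e-16), but per 100 pan-T counts it read 1.44 ± 0.0315 and 6.52 ± 0.279 (-2.18). Ikzf2, which encodes Helios, went from 1.05 to -2.36 between the scalings, Il2ra, the high-affinity IL-2 receptor chain CD25, from 1.84 to -1.57, and Ctla4, an inhibitory receptor of Treg cells, from 2.31 to -1.10. In the Treg core list 15 of 18 rose and 1 fell (16 and 1 by the list alone; FDR 8.14e-11), while all 18 were lower per pan-T count. Il2rb rose 8.61-fold and Tnfrsf4 5.30-fold by CPM, and both were lower per pan-T count (-0.30 and -1.0). Nrp1, a thymic Treg marker that myeloid cells also express, turned from 0.46 to -2.95, and the thymic Treg list was not called (3 of 6 rose and 1 fell, 4 and 1 by the list alone; FDR 0.131), with all 6 lower per pan-T count.

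**Figure D2:**
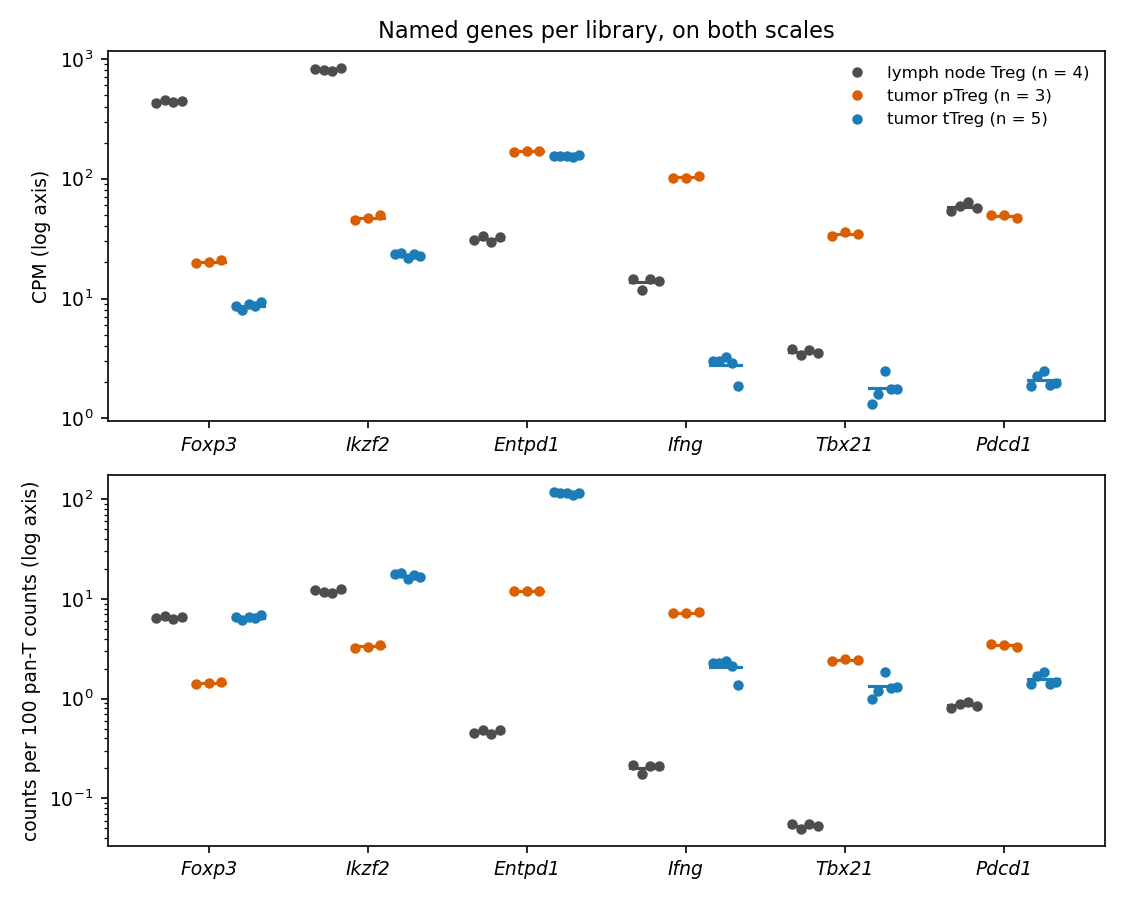
Levels of Foxp3, Ikzf2, Entpd1, Ifng, Tbx21 and Pdcd1 in each library, above as CPM and below as counts per 100 pan-T counts, on log axes with lines at group means. Foxp3 and Ikzf2 were higher in tumor pTreg than in tumor tTreg by CPM and lower per pan-T count, and Entpd1 turned the same way, while Ifng, Tbx21 and Pdcd1 were higher in tumor pTreg on both scales.

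Entpd1 encodes CD39, the ectoenzyme that breaks extracellular ATP and ADP down to AMP. Its level was close in the tumor groups, 169.5 ± 2.12 CPM in tumor pTreg and 154.7 ± 1.99 in tumor tTreg (log2 fold change 0.14, adjusted p = 1.85e-04), and lower in tumor pTreg per pan-T count (-3.27; 11.98 ± 0.0398 against 115.5 ± 2.37 per 100). Nt5e, the gene of CD73, which turns AMP into adenosine, was 4.6-fold higher in tumor pTreg by CPM and lower per pan-T count (-1.21). In the purine list 8 of 16 genes rose and 4 fell, all 16 were lower per pan-T count, and the list was not called (FDR 0.131). Il10, a suppressive cytokine, differed little by CPM (22.6 ± 1.52 against 19.1 ± 1.40; log2 fold change 0.25, adjusted p = 0.0045) and was lower per pan-T count (-3.16). Both Entpd1 and Il10 are also made by macrophages, whose markers were level between the tumor groups: Csf1r, the receptor that keeps macrophages alive, read 893 ± 9.43 against 857 ± 19.9 CPM and was not called (adjusted p = 0.0601), though lower per pan-T count (-3.34).

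Receptor lists rose by CPM. Tumor Treg genes rose in 18 of 20 cases with none lower (FDR 6.62e-12), co-stimulatory receptors in 10 of 10 (FDR 2.93e-11), co-inhibitory receptors in 9 of 11 with none lower (FDR 7.14e-07) and suppressive effector genes in 12 of 14 with 1 lower (FDR 2.17e-05). Per pan-T count the same lists held 1, 2, 1 and 1 higher members against 19, 8, 10 and 13 lower. Icos, a co-stimulatory receptor, rose 8.46-fold (152 ± 5.11 against 18.0 ± 1.37 CPM) and Ccr8, a chemokine receptor of tumor Treg cells, 6.68-fold, yet both were lower per pan-T count (-0.33 and -0.67), while Cd28 rose 13.8-fold and stayed higher (0.38). Chemokine receptors rose in 12 of 16 cases and fell in 2 (3 by the list alone; FDR 0.000211), and genes of the IL-2 and STAT5 response in 8 of 12 with 2 lower (FDR 0.000139), but per pan-T count 1 chemokine receptor was higher and 14 lower, and all 12 IL-2 and STAT5 genes were lower. Genes of T cell receptor and NF-kB activation rose in 15 of 18 cases and fell in 2 (16 rises by the list alone; FDR 4.05e-08), and all 18 were lower per pan-T count. Cd69, an early activation gene of that list, rose 4.67-fold by CPM and was lower per pan-T count (-1.18).

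Several called lists lost the call when the correlation between genes was estimated. Interferon gamma response genes rose in 15 of 23 cases and fell in 4 (FDR 0.00429; adjusted p = 0.0658 with the estimated correlation), and all 23 were lower per pan-T count. Nlrc5, the activator of MHC class I genes, rose 1.98-fold and Psmb8, an immunoproteasome subunit, 1.44-fold, and both were lower per pan-T count (-2.43 and -2.88). Naive and lymph node homing genes rose in 11 of 16 cases and fell in 3 (FDR 0.000849; adjusted p = 0.134), TGF-beta response genes in 9 of 11 with 1 lower (FDR 0.000289; adjusted p = 0.0567) and dissociation stress genes in 13 of 16 with 1 lower (FDR 0.00082; adjusted p = 0.101). Per pan-T count 15 of the naive genes, all 11 TGF-beta genes and all 16 stress genes were lower. Hspa1a, a heat shock gene of the stress list, rose 1.60-fold by CPM and was lower per pan-T count (-2.73). Oxidative phosphorylation genes fell in 19 of 26 cases with none higher (21 by the list alone; FDR 3.27e-05; adjusted p = 0.204), with Atp5b, an ATP synthase subunit, down to a log2 fold change of -0.25. Ribosomal protein genes fell in 41 of 81 cases and rose in 4 (42 and 4 by the list alone; FDR 0.000458; adjusted p = 0.65), and per pan-T count all 26 oxidative phosphorylation and all 81 ribosomal genes were lower. The estimated correlation left 14 of 21 called lists in place, and fry, which tests whether a set moves one way, called 30.

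Tumor and stromal markers were lower in tumor pTreg than in tumor tTreg. Of 10 hepatocyte genes 8 fell (9 fell and 1 rose by the list alone; FDR 0.000393), with the serum protein genes Alb and Trf at log2 fold changes of -0.51 and -0.54 and the keratin gene Krt18 at -0.53. Fibroblast markers fell in 7 of 9 cases and rose in 2 (FDR 0.00215), and 1 of the rising members, Thy1, is also a T cell gene. Macrophage genes were not called as a list (1 rose and 4 fell of 14, FDR 0.658), nor were dendritic cell genes (3 rose and 6 fell of 11, 7 by the list alone; FDR 0.137). Lists for hypoxia, fatty acid use, type I interferon, neutrophils, B cells and erythroid cells had medians and means, or medians and tests, of opposite sign and were not called.

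**Figure D3:**
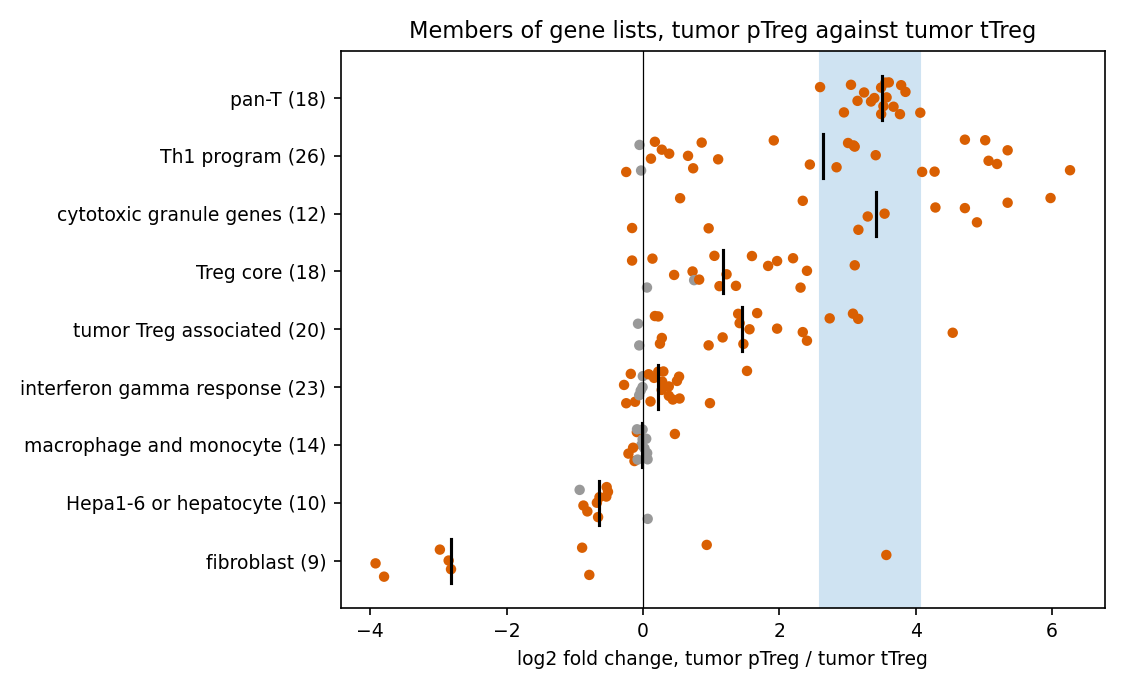
Log2 fold changes of tumor pTreg over tumor tTreg by CPM for the members of 9 gene lists. Orange points were called, grey points were not, black bars mark list medians, and the blue band spans the range of the pan-T genes. Members of the Treg core, tumor Treg and interferon gamma lists that lie below the band were lower in tumor pTreg per pan-T count, and the Th1 and cytotoxic members above it were higher.

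Because tTreg donors carried CD45.1, genes near Ptprc (chromosome 1, 138062861 to 138175708 in GRCm38), which encodes CD45, may differ by strain. Of 216 genes within 20 Mb of it 111 were called between the tumor groups, 51.4% against 52.4% elsewhere (odds ratio 0.961, Fisher exact p = 0.784). Their median absolute log2 fold change was 0.24 against 0.206 in 10000 random sets of equal size, at percentile 95.5, and the percentile was 97.5 for genes within 10 Mb and 99.8 within 40 Mb. T cell transcripts were few in tumor tTreg (pan-T genes 134 ± 2.41 CPM against 6766 ± 53.3 in lymph node Treg). The Fisher test therefore cannot exclude a strain effect in T cells. Ptprc itself was 1.67-fold higher in tumor pTreg by CPM (802 ± 21.4 against 484 ± 11.5) and lower per pan-T count (-2.67).

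What separates tumor pTreg from lymph node Treg? Entpd1 (chromosome 19, 40612366 to 40741602) was 5.79-fold higher in tumor pTreg, at 169.5 ± 2.12 (n = 3) against 31.5 ± 1.57 CPM (n = 4; adjusted p = 2.17e-30), and Nt5e (chromosome 9, 88327197 to 88372092) was 8.25-fold lower, at 39.0 ± 1.71 against 346 ± 7.95. Ifng (chromosome 10, 118441046 to 118445892) rose 7.98-fold from 13.8 ± 1.28 CPM and Tbx21 (chromosome 11, 97098071 to 97115331) rose 10.2-fold from 3.61 ± 0.192. Foxp3 (X chromosome, 7573644 to 7595245) fell 20.1-fold from 441 ± 11.1 CPM, Ikzf2 16.02-fold from 816 ± 24.5 and Il2ra 11.1-fold from 705 ± 6.42. Each of these kept its direction per pan-T count, with Entpd1 at 4.69, Nt5e at -0.89, Ifng at 5.15, Tbx21 at 5.51, Foxp3 at -2.18, Ikzf2 at -1.85 and Il2ra at -1.32. This scaling moves every gene upward against lymph node Treg, and 14338 of all 15705 genes were higher on it. The rises of Entpd1, Ifng and Tbx21 could therefore not have turned, whereas the falls of Nt5e, Foxp3, Ikzf2 and Il2ra could have. Il10 rose as well (log2 fold change 0.81). Ctla4 (-1.77), Nrp1 (-0.64), Ccr8 (-0.57), Pdcd1 (-0.16, adjusted p = 0.0045) and Ptprc (-1.76) were lower by CPM but higher per pan-T count, at 0.39, 1.51, 1.59, 2.0 and 0.39. Cxcr3 was level by CPM (23.4 ± 1.09 against 26.2 ± 1.62, adjusted p = 0.39) and higher per pan-T count (2.10).

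Alb, the serum albumin gene, stood first among the genes higher in tumor pTreg by the same limits. It had 3 counts over the lymph node libraries, all in replicate 4, and a ratio of 47800 (95% interval 16360 to 231800). For genes without lymph node counts only a lower bound can be given: at least 6682-fold for Aldh1a1, 6518 for Itih2, 4548 for Faim2, 3998 for Fmod, 3879 for Ccl24, 3426 for Slco1a4 and 3116 for Hspb8. At the other end Kcna2 had no counts in tumor pTreg against 13.5 ± 1.37 CPM (at least 243.5-fold lower), Slc28a2b was 1114-fold lower (interval 381 to 5406) and Gata1 460.2-fold lower (interval 157 to 2234), with 3 counts each. Gpr83, a receptor of the Treg signature, fell from 163 ± 3.04 to 0.610 ± 0.290 CPM (247-fold), St8sia6 from 159 ± 4.96 to 0.719 ± 0.108 (204-fold), Arhgap20 212-fold, Kcnf1 131-fold and Tet1 105-fold, and these stayed lower per pan-T count. The intervals cover counting error only. By CPM 7482 genes were higher and 6253 lower in tumor pTreg, by at least 2-fold 4712 and 2785, and per pan-T count 14338 and 656, with a median shift of 2.27.

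Treg and naive programs fell in tumor pTreg. In the Treg core list 16 of 18 fell and 2 rose (FDR 1.97e-05), while per pan-T count 8 rose and 8 fell, and Izumo1r, the folate receptor 4 gene of Treg cells, fell 29.4-fold (316 ± 12.7 to 9.99 ± 0.827 CPM; -2.72 per pan-T count). Adjustment over each list alone gave the same counts in this comparison. Naive and lymph node homing genes fell in 15 of 16 cases (FDR 7.46e-06; adjusted p = 0.0764 with the estimated correlation), and per pan-T count 5 were higher and 11 lower. Satb1, a chromatin organizer of resting T cells, fell 10.2-fold (574 ± 9.99 to 52.1 ± 2.14 CPM) and stayed lower per pan-T count (-1.20). Of 10 co-stimulatory receptors 9 fell and none rose (FDR 0.000855), whereas 7 were higher and 2 lower per pan-T count, with Cd27 lower on both scales (15.3-fold by CPM, -1.78). Thymic Treg genes fell in 5 of 6 cases (FDR 0.0248; adjusted p = 0.121) and B cell markers in 8 of 10 with none higher (FDR 0.00487; adjusted p = 0.103), whereas per pan-T count 3 thymic Treg genes were higher and 3 lower and 3 B cell markers higher and 5 lower. Ighm, an immunoglobulin heavy chain gene, went from 386 ± 6.32 to 59.9 ± 2.02 CPM.

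Th1 and cytotoxic genes rose over lymph node Treg. Counts of list members per pan-T count are to be read beside the 14338 of all 15705 genes that were higher on that scale. The Th1 program rose in 18 of 26 cases and fell in 6 (FDR 0.0406; adjusted p = 0.121), and per pan-T count in 25 with 1 lower. Ccl3 and Ccl4, chemokines that macrophages also make, rose from 0.211 ± 0.119 and 0.236 ± 0.170 to 203 ± 5.96 and 140.5 ± 3.11 CPM, and Bhlhe40, a factor of cytokine-producing T cells, rose 7.03-fold. Cytotoxic genes rose in 11 of 12 cases and fell in 1 (FDR 0.0235; adjusted p = 0.121) and all 12 per pan-T count, including Nkg7 (6.11-fold) and Gzmk, with 2 counts in lymph node Treg and a ratio of 445 (95% interval 123 to 3681). Interferon gamma response genes fell in 17 of 23 cases and rose in 4 (FDR 0.00186; adjusted p = 0.0764), yet all 23 were higher per pan-T count. Nlrc5 was lower by CPM (-1.82) and higher per pan-T count (0.33), and Gbp3, a guanylate-binding protein, rose 3.87-fold. Macrophage markers rose beside them in 14 of 14 cases (FDR 1.78e-05), with Csf1r 403-fold and C1qa, a complement gene, 745-fold higher, and hepatocyte markers in 10 of 10 (FDR 0.000162), with Trf 660-fold higher.

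Metabolic lists rose in the same libraries. Glycolysis genes rose in 15 of 17 cases and fell in 2 (FDR 0.000788; adjusted p = 0.121), with Hk2, hexokinase 2, 29.1-fold and Tpi1 13.3-fold higher. Hypoxia genes rose in 14 of 16 with 1 lower (FDR 0.00282), with the angiogenic factor Vegfa 120.0-fold and the mitophagy gene Bnip3 15.5-fold higher, and lipid and cholesterol synthesis genes in 19 of 20 with 1 lower (FDR 0.000243), with the desaturase gene Scd1 124-fold higher. Cell cycle genes rose in 24 of 25 cases and fell in 1 (FDR 0.00064; adjusted p = 0.121), with Mki67 2.04-fold and Top2a 1.92-fold higher. Oxidative phosphorylation genes rose in 20 of 26 with none lower (FDR 0.0248; adjusted p = 0.475), and dissociation stress genes in 14 of 16 with 2 lower (FDR 0.00282; adjusted p = 0.121), with Atf3 272-fold higher. Fibroblast markers rose in 8 of 9 cases (FDR 0.0248; adjusted p = 0.103) and dendritic cell markers in 8 of 11 with 2 lower (FDR 0.0248; adjusted p = 0.121), led by the MHC class II chaperone Cd74 (67.5-fold). Ribosomal protein genes fell in 63 of 81 cases and rose in 7 (FDR 1.97e-05; adjusted p = 0.48), but 80 were higher per pan-T count. The rising metabolic, cell cycle and stress lists were higher throughout per pan-T count. So were 14338 of all 15705 genes tested, so this does not show a rise in T cells. Of the 19 lists called 6 kept the call with the estimated correlation, namely Treg core, co-stimulatory, hypoxia, lipid, hepatocyte and macrophage genes. The tumor Treg, Th2, chemokine receptor and type I interferon lists had medians and means, or medians and tests, of opposite sign and were not called.

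How did tTreg in the tumor compare with lymph node Treg? Entpd1 was 5.26-fold higher in tumor tTreg (154.7 ± 1.99, n = 5, against 31.5 ± 1.57 CPM, n = 4; adjusted p = 7.45e-31) and higher per pan-T count (7.95). Foxp3 was 47.1-fold lower by CPM (8.74 ± 0.478 against 441 ± 11.1), but equal per 100 pan-T counts, at 6.52 ± 0.279 against 6.52 ± 0.175 (adjusted p = 0.977). Ikzf2 was 33.1-fold lower by CPM and higher per pan-T count (0.51; 17.2 ± 0.842 against 12.1 ± 0.458 per 100). Il2ra (39.7-fold), Nt5e (37.97-fold), Ctla4 (16.9-fold) and Il2rb (32.6-fold) were lower by CPM but higher per pan-T count, at 0.25, 0.31, 1.48 and 0.53. The same turn was seen in Ifng (-2.20 to 3.36), Tbx21 (-0.92 to 4.63), Cxcr3 (-2.51 to 3.05), Pdcd1 (-4.70 to 0.86), Ccr8 (-3.31 to 2.25), Nrp1 (-1.10 to 4.46) and Ptprc (-2.50 to 3.06). Il10 rose on both scales (0.56 and 6.12). As the scaling to pan-T counts moves every gene upward here, the rises of Entpd1 and Il10 by CPM could not have turned.

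Alb again stood first among the genes higher in tumor tTreg. It had a ratio of 68570 over the 3 lymph node counts (95% interval 23460 to 332500), and lower bounds were 9440-fold for Aldh1a1, 7542 for Itih2, 7468 for Faim2, 6874 for Col3a1, 5977 for Fmod, 4402 for Ccl24 and 4266 for Tinagl1. The genes furthest lower were Nsg2, from 295 ± 4.81 to 0.131 ± 0.0488 CPM (log2 fold change -10.96), Gpr83 (-8.70), Gata1 (-8.59), St8sia6 (-8.19) and Kcnf1 (-8.10). Slc28a2b, with 3 counts in tumor tTreg, was 1880.0-fold lower (interval 643 to 9118), Vmn2r84, with 2, 784-fold (interval 217 to 6485) and Kcna2, with 2, 613-fold (interval 169 to 5068). Each stayed lower per pan-T count. By CPM 7550 genes were higher and 6637 lower in tumor tTreg, by at least 2-fold 4874 and 3529, and per pan-T count 15208 and 147, with a median shift of 5.66.

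T cell programs were lower by CPM and mostly higher per pan-T count, as 15208 of all 15705 genes were on that scale. Treg core genes fell in 16 of 18 cases and rose in 2 (FDR 3.22e-05), but 15 were higher and 2 lower per pan-T count. Co-stimulatory receptors fell in 10 of 10 (FDR 5.85e-05), with 7 higher and 2 lower per pan-T count, such as Icos (-4.04 to 1.52) and Cd28 (-5.17 to 0.39), and follicular helper genes fell in 10 of 11 with 1 higher (FDR 0.00318), led by Btla, an inhibitory receptor lower on both scales (-7.16 and -1.60), while 4 members of the list were higher and 3 lower per pan-T count. Naive and homing genes fell in 15 of 16 (FDR 3.22e-05; adjusted p = 0.086 with the estimated correlation) and were higher in 13 and lower in 2 per pan-T count, though Satb1 (-6.85) stayed lower (-1.29). Tumor Treg genes fell in 13 of 20 cases and rose in 7 (FDR 0.025; adjusted p = 0.199), and all 20 were higher per pan-T count. Havcr2, the TIM-3 receptor gene that macrophages also express, rose 10.7-fold. Interferon gamma response genes fell in 19 of 23 and rose in 4 (FDR 0.00228; adjusted p = 0.0733), with all 23 higher per pan-T count. Th2 genes fell in 7 of 9 with 1 higher (FDR 0.0229; adjusted p = 0.118), among them Gata3 (-5.14, turning to 0.42 per pan-T count), IL-2 and STAT5 genes in 9 of 12 with 3 higher (FDR 0.0274; adjusted p = 0.17), thymic Treg genes in 5 of 6 (FDR 0.0344; adjusted p = 0.17) and B cell markers in 8 of 10 (FDR 0.00989; adjusted p = 0.122). Per pan-T count these lists held 8, 11, 4 and 7 higher members against 0, 0, 1 and 0 lower. Th1 genes were not called as a list (9 rose and 17 fell of 26, FDR 0.139), nor were cytotoxic genes (4 rose and 6 fell of 12, FDR 0.374), although 25 Th1 and all 12 cytotoxic genes were higher per pan-T count.

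Non-lymphoid and metabolic lists rose as in tumor pTreg. Macrophage markers rose in 14 of 14 cases (FDR 3.22e-05), with C1qa 812-fold and Lyz2, a lysozyme gene of myeloid cells, 59.3-fold higher, and hepatocyte markers in 10 of 10 (FDR 0.00025), with Trf 959-fold higher. Fibroblast markers rose in 8 of 9 (FDR 0.0208; adjusted p = 0.09) and dendritic cell markers in 8 of 11 with 1 lower (FDR 0.0344; adjusted p = 0.17). Lipid synthesis genes rose in 18 of 20 with 2 lower (FDR 0.000996), with Scd1 at 196 ± 5.60 against 1.15 ± 0.186 CPM, glycolysis genes in 14 of 17 with 2 lower (FDR 0.00387; adjusted p = 0.17), with Hk2 25.9-fold higher, and hypoxia genes in 14 of 16 with 2 lower (FDR 0.0069; adjusted p = 0.054), with Vegfa 132-fold higher. Cell cycle genes rose in 22 of 25 cases with 1 lower (FDR 0.00228; adjusted p = 0.17), oxidative phosphorylation genes in 23 of 26 with 2 lower (FDR 0.00387; adjusted p = 0.343) and dissociation stress genes in 14 of 16 with 2 lower (FDR 0.00817; adjusted p = 0.17). Ribosomal protein genes fell in 55 of 81 cases and rose in 16 (54 and 16 by the list alone, which left the counts of all other lists as they were; FDR 0.0046; adjusted p = 0.627), but all 81 were higher per pan-T count. Of 21 lists called 6 kept the call with the estimated correlation, namely Treg core, co-stimulatory, follicular helper, lipid, hepatocyte and macrophage genes. Suppressive effector, type I interferon and TGF-beta genes had medians and means of opposite sign and were not called.

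Did the tumor groups differ from lymph node Treg in the same genes? Their log2 fold changes against lymph node Treg correlated at r = 0.974 across 15705 genes, which are not independent replicates, and 7087 genes were higher and 5980 lower in both, with 173 called in opposite directions. Hepatocyte markers (25.3 to 9696 and 12160 CPM) and macrophage markers (39.7 to 6261 and 6507 CPM) rose in both groups alongside, so the correlation includes transcripts of other cells. Both comparisons use the same 4 lymph node libraries, and simulated groups without any change gave r = 0.509 (0.469 to 0.545 in 20 simulations) with a covariance of 0.0694 against the observed 9.87. When each tumor group was set against a separate pair of lymph node libraries r was 0.957 to 0.959 and the covariance 10.02 to 10.03. Independent calls would have overlapped in 3597 higher and 2643 lower genes, and the simulations gave no overlap. Genes that rose in both groups included Entpd1, Hk2, Vegfa and Csf1r, and genes that fell in both included Foxp3, Ikzf2, Il2ra, Nt5e and Satb1, although Foxp3 was level and Ikzf2, Il2ra and Nt5e were higher in tumor tTreg per pan-T count.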

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

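The tests of explanations in this part were chosen after the results were seen, and the comparison with other groupings of the libraries was planned before. In 203 groups of values (103 genes and 4 library measures, in lymph node Treg and tumor tTreg, without groups where all libraries read the same) 10 held a library standing apart from the others. About 1 in 20 groups, or 10.2, would do so by chance. Alb read 0.1743 CPM in lymph node replicate 4 and 0 in the others, and Vmn2r84 0.1095 CPM in tumor tTreg replicate 4 and 0 in the others, which are 3 and 2 counts. Ifng read 1.878 CPM in tumor tTreg replicate 5 against 2.903 to 3.241, Havcr2 49.78 in replicate 2 against 52.76 to 53.07, Ccl4 176.7 in replicate 4 against 163.5 to 166.7 and Aldh1a1 402.7 in replicate 1 against 431.1 to 436.6. In lymph node Treg Cd27 read 198.7 CPM in replicate 1 against 207.8 to 209.4, Slc28a2b 64.25 in replicate 1 against 60.54 to 61.07 and Fasl 8.367 in replicate 4 against 7.62 to 7.685. Lymph node replicate 2 had a total of 14.57 M counts against 17 to 17.32 M. All of these libraries were kept.

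A set of 12 named genes was called in opposite directions against lymph node Treg, higher in tumor pTreg and lower in tumor tTreg by CPM, and the tumor groups differed in each of them in a direct test. The differences were 7.16 for Il13 (4.87 against -2.29), 6.62 for Il21 (5.23 against -1.39), 6.26 for Eomes (4.29 against -1.97), 5.35 for Fasl (1.47 against -3.88), 5.19 for Ifng (3.00 against -2.20), 5.14 for Tnfsf11 (1.15 against -3.99) and 5.14 for Cd8a (1.62 against -3.52). They were 5.02 for Cxcr6 (1.91 against -3.11), 4.72 for Nkg7 (2.61 against -2.11), 4.28 for Tbx21 (3.36 against -0.92), 3.41 for Il18rap (1.43 against -1.98) and 2.34 for Gzmb (0.93 against -1.42). Per pan-T count all 12 lay above lymph node Treg in both tumor groups, in tumor tTreg by 3.01 for Il13, 4.03 for Il21, 3.53 for Eomes, 1.66 for Fasl, 3.36 for Ifng, 1.57 for Tnfsf11, 2.03 for Cd8a, 2.44 for Cxcr6, 3.45 for Nkg7, 4.63 for Tbx21, 3.58 for Il18rap and 4.14 for Gzmb. The scaling fixed this outcome, since 14338 of all 15705 genes in tumor pTreg and 15208 in tumor tTreg were higher on it. Opposite directions were thus seen by CPM only, and the turn does not show a rise in T cells.

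Treg core genes were lower in the tumor libraries than in lymph node Treg by CPM. If RNA of other cells filled most of the tumor libraries, the pan-T genes should fall as far: their median in tumor tTreg was -5.621 (SD 0.530 over genes) beside -4.617 for the Treg core, so this explanation stays possible there. A large fall of Foxp3 per T cell transcript in tumor tTreg is argued against, since the change was 0.001553 per pan-T count and 0.20 per CD3 count. A fall within the spread of the pan-T genes (SD 0.530) cannot be excluded, because the value depends on the T cell genes used for scaling. In tumor pTreg the same change was -2.179 (SD of the pan-T genes 0.542), so a lower Foxp3 share stays possible there. Library totals do not tell lower Foxp3 in each cell from T cells lacking Foxp3 among the sorted cells, which protein staining of sorted cells or RNA sequencing of individual cells could.

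Ifng and Tbx21 were higher in tumor pTreg than in tumor tTreg. A larger T cell share as the whole cause would bring both to 0 per pan-T count. Tbx21 read 0.8757 and Ifng 1.789 (SD of the pan-T genes 0.356), which argues against it, more clearly for Ifng than for Tbx21. Both values depend on the T cell genes used for scaling. CD8 T cells among the sorted cells would bring Cd8a and Cd8b1 above 0 per pan-T count, and these read 1.744 and 0.9972, so CD8 T cells may account for part of the difference. T cells lacking Foxp3 among the sorted cells were not tested as a source of Ifng and Tbx21 and stay possible. Foxp3 read 1.44 per 100 pan-T counts in tumor pTreg against 6.52 in tumor tTreg. Counting the Cd8a-positive and the Foxp3-negative cells that carry Ifng transcripts in the sorted cells would tell these sources apart.

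Entpd1 was higher in both kinds of tumor libraries than in lymph node Treg. T cells as its main source, at 1 level per T cell transcript, would move it between the tumor groups as the pan-T genes moved, but it lay 2.459 below the lowest of them (2.598), which excludes that. Macrophage RNA stays possible, since Entpd1 lay 0.153 from the median of the macrophage markers (-0.014, SD 0.160, range -0.213 to 0.468). Most hepatocyte markers argue against Hepa1-6 RNA as the main source, with Entpd1 0.7874 above their median (-0.648, SD 0.279). Their range was -0.929 to 0.069. The highest was Apoe (4072 ± 22.6 CPM in tumor pTreg against 3901 ± 95.9 in tumor tTreg). It moved as the macrophage marker Csf1r did (893 ± 9.43 against 857 ± 19.9 CPM), so it may not reflect Hepa1-6 RNA. The Hepa1-6 source is still not excluded. Medians of the neutrophil (0.0545), NK (0.219) and endothelial (0.226) markers between the tumor groups also lay near Entpd1, so the test does not single out macrophages. A higher Entpd1 level per T cell transcript in tumor tTreg than in tumor pTreg was not tested. Macrophages may supply part of the Entpd1 transcripts in the tumor libraries, and staining for CD39 on Foxp3-positive cells and on macrophages would test this.

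Other groupings of the libraries called fewer genes than the real groupings. Between the tumor groups 1 of 56 groupings, the real one, called as many as 8184 genes and the next highest called 1. A chance split of these libraries is therefore excluded. For tumor pTreg against lymph node Treg it was 1 of 35 (13735 genes, next highest 10131), and for tumor tTreg against lymph node Treg 1 of 100 drawn of 126 (14187, next highest 9700). A chance split is excluded for these as well. The high counts of the runners-up came from nearly mirrored groupings that moved 3 and 4 libraries. This points to the sample structure of groups lying far apart. Chance differences between animals or preparations cannot be excluded this way, because the labels do not say that the libraries came from separate animals.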

How the results depend on the processing

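Many directions depend on whether libraries are scaled to all counts or to T cell counts. Scaling to pan-T counts and to the 4 CD3 genes was chosen after seeing the data, and all others before. Of 3683 gene results under the alternatives set in advance 3667 stayed the same, 2 were weaker, 13 were stronger and 1 was reversed (Ddx3y in tumor pTreg versus tumor tTreg, 0.00836 without tumor pTreg replicate 1 and down to -0.0427 without tumor tTreg replicate 3, not called in either), and the cause was not tested. Xist between the tumor groups and Cd8b1 in tumor pTreg against lymph node Treg lost the call with FPKM + 0.1. Of 1623 list results 1562 stayed the same, 47 were weaker and 14 stronger. With a filter at a mean of 5 CPM 15 lists instead of 19 were called in tumor pTreg against lymph node Treg, where thymic Treg, Th1, cytotoxic and fibroblast genes lost the call, and 16 instead of 21 in tumor tTreg, where thymic Treg, Th2, IL-2 and STAT5 and fibroblast genes lost it. The B cell list kept too few members to be tested in either, and follicular helper genes gained the call in tumor pTreg. The Th17 list lost the call between the tumor groups with that filter (adjusted p = 0.227). Calling genes by at least 2-fold left 1031 higher and 222 lower between the tumor groups, 4712 and 2785 in tumor pTreg and 4874 and 3529 in tumor tTreg against lymph node Treg. An estimated correlation left 6 called lists and fry called 38 in each comparison with lymph node Treg. RLE factors and DESeq2 gave 3572 and 3328 genes higher against 4872 and 4315 lower between the tumor groups. The odds ratio near Ptprc crossed 1 at 10 Mb (1.151) and at 40 Mb (1.21, Fisher exact p = 0.0614). With separate pairs of lymph node libraries for each tumor group r was 0.958, 0.959, 0.9583, 0.9588, 0.9575 and 0.9574. With each library left out in turn 3772 to 4169 genes were higher and 3390 to 3972 lower between the tumor groups, and Entpd1 stayed at 0.132 to 0.148 there, at 2.51 to 2.55 in tumor pTreg and at 2.37 to 2.42 in tumor tTreg against lymph node Treg.

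Replicate numbers carried no sign of pairing: over 9623 genes the correlation of equal numbers was -0.0585, 0.0205 and 0.0441 between the tumor groups, -0.0162, 0.0138 and -0.0344 for tumor pTreg with lymph node Treg and -0.0482 to 0.0563 for tumor tTreg with lymph node Treg. With the replicate number as a block 3664 genes were higher and 3544 lower between the tumor groups, 7222 and 6299 in tumor pTreg and 7426 and 6611 in tumor tTreg against lymph node Treg. Under the block 21 lists were called between the tumor groups, where the Th17 list lost the call (adjusted p = 0.0608) and plasma cell markers gained it (0.0495). Against lymph node Treg 21 lists instead of 19 were called in tumor pTreg, with follicular helper genes (0.0356) and erythroid markers (0.0452) added, and 22 instead of 21 in tumor tTreg, with chemokine receptors added (0.0488).

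Scaling to pan-T counts gave 80 genes higher and 15266 lower between the tumor groups, 14338 and 656 in tumor pTreg and 15208 and 147 in tumor tTreg against lymph node Treg. CD3 scaling gave 61 and 15305, 14354 and 608, and 15251 and 123. The change of sign follows from the different T cell shares by construction. Between the tumor groups the log2 fold changes turned to -2.18 for Foxp3 (-2.33 by CD3), -3.27 for Entpd1 (-3.43 by CD3), -1.21 for Nt5e, -0.96 for Cxcr3, -2.36 for Ikzf2, -2.95 for Nrp1, -1.57 for Il2ra, -1.10 for Ctla4, -2.67 for Ptprc, -3.16 for Il10, -0.67 for Ccr8, -0.30 for Il2rb, -0.33 for Icos, -1.0 for Tnfrsf4, -1.06 for Gzmb, -3.34 for Apoe, -3.34 for Csf1r, -2.43 for Nlrc5, -2.88 for Psmb8, -1.18 for Cd69, -2.73 for Hspa1a and -0.81 for Cd2, and Il18rap and Ctsw lost the call. In tumor pTreg against lymph node Treg they turned to 2.10 for Cxcr3, 1.51 for Nrp1, 0.39 for Ctla4, 0.39 for Ptprc, 1.59 for Ccr8, 2.0 for Pdcd1, 0.70 for Ddx3y, 1.78 for Cd8b1 and 0.33 for Nlrc5. In tumor tTreg against lymph node Treg they turned to 0.00155 for Foxp3 (0.20 by CD3), 0.31 for Nt5e, 4.63 for Tbx21, 3.05 for Cxcr3, 3.36 for Ifng, 0.51 for Ikzf2, 4.46 for Nrp1, 0.25 for Il2ra, 1.48 for Ctla4, 3.06 for Ptprc, 2.25 for Ccr8, 0.86 for Pdcd1, 0.53 for Il2rb, 0.39 for Cd28, 4.13 for Ddx3y, 2.03 for Cd8a, 0.78 for Cd8b1, 0.42 for Gata3 and 1.52 for Icos.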

Other observations

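Sex-linked genes separated the tumor libraries from the lymph node libraries. Xist, the RNA that silences the second X chromosome in females, read 0.180 ± 0.102 CPM in lymph node Treg, 1102 ± 8.33 in tumor pTreg and 1201 ± 47.9 in tumor tTreg. Ddx3y, a Y-linked helicase gene, read 202 ± 6.15, 68.9 ± 2.15 and 70.1 ± 3.49 CPM and was lower in the tumor groups by CPM but higher per pan-T count (0.70 in tumor pTreg and 4.13 in tumor tTreg). Lymph node libraries thus read as male, with Ddx3y and almost no Xist, whereas tumor libraries held both Xist and Y-linked transcripts. In both comparisons with lymph node Treg, sex therefore cannot be told apart from tissue. The sex of lymph node donors, cell donors and hosts is not given in the sources used here. Of their genotypes, only the TCRbd-/- hosts, the CD45.1 tTreg and the CD45.2 conventional CD4 T cells are named. The sex-linked list was not called in any comparison, with 1 of 5 genes higher and 1 lower between the tumor groups (FDR 0.802) and 1 higher and 4 lower in each tumor group against lymph node Treg (FDR 0.0748 in tumor pTreg and 0.0995 in tumor tTreg, with median and mean of opposite sign).

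Several lists were not called between the tumor groups, and per pan-T count none of them had a higher member. There neutrophil, B cell and erythroid markers had no called member (FDR 0.802 for each), plasma cell markers fell in 3 of 3 cases (FDR 0.0636), NK markers rose in 3 of 6 and fell in 1 (FDR 0.567; 2 by the list alone) and endothelial markers rose in 3 of 7 and fell in 1 (FDR 0.393). Type I interferon genes rose in 6 of 23 and fell in 8 (FDR 0.802), fatty acid genes rose in 4 of 12 and fell in 5 (FDR 0.744) and mitochondrially encoded genes rose in 2 of 15 and fell in 8 (FDR 0.131; 10 by the list alone). Cell cycle genes rose in 7 of 25 and fell in 2 (FDR 0.658), and lipid synthesis genes rose in 4 of 20 and fell in 11 (FDR 0.0662). Of these lists B cell, cell cycle and lipid synthesis genes were called against lymph node Treg in both tumor groups, and the others in no comparison by the same test, although plasma cell and erythroid markers were called under some alternatives (plasma cell adjusted p = 0.0495 between the tumor groups with a replicate block). Neutrophil markers summed to 4.73 ± 0.463 CPM in lymph node Treg, 455 ± 11.7 in tumor pTreg and 448 ± 17.7 in tumor tTreg, NK markers to 12.2 ± 0.528, 321 ± 5.29 and 332 ± 21.2 and endothelial markers to 190.1 ± 2.49, 58.9 ± 3.33 and 49.1 ± 1.45. The endothelial sums do not reflect most members, since 6 of 7 were higher and 1 lower by CPM in each tumor group against lymph node Treg.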
